A study of Mus musculus with 16 samples.

How the data were processed

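The samples were whole retinas of C57 and BALBc mice at day 12 after birth, kept in 75% oxygen from day 7 (hyperoxia) or in room air (normoxia), with 4 libraries in each of 4 groups. Per the labels' protocols, total RNA was extracted with TRIzol and libraries were made with the NEBNext Ultra II kit. Per the submitters' processing notes, reads were aligned to GRCm38 (mm10) with HISAT2 2.0.5 and counted per gene with featureCounts 1.5.0-p3. The strand setting of the counting is not given. The deposited file holds FPKM values, made by the authors, for 54532 genes in 16 libraries. Of these genes, 54495 were matched by identifier to the GENCODE mouse annotation, release 21, and 27 symbols that a spreadsheet had turned into dates were restored from the identifiers.

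Reads per library were recovered by finding the FPKM step that corresponds to 1 read. Between 97.1% and 97.5% of values were then whole numbers of reads, within a tolerance of 0.01 and for values up to 1000 reads. The ratio of recovered reads to the library size implied by the step was between 0.884 and 1.15. Recovered reads came to between 16.7 M and 29.7 M (mega) per library. Pearson correlations between libraries of the same group, across genes, were between 0.937 and 0.979.

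Values were analysed as log2(FPKM + 0.5), for the 14953 genes with at least 1 FPKM in at least 4 libraries. The added 0.5 makes log2 changes smaller than the ratio of FPKM means for genes with a group near or below it. One linear model with the 4 groups was fitted with limma 3.58.1, using empirical Bayes moderation with a mean-variance trend. The 5 comparisons were hyperoxia against normoxia in each strain, the difference of those responses, and BALBc against C57 in each oxygen condition. Tests were two-sided, and p-values were adjusted over all tested genes by the Benjamini-Hochberg method, with a threshold of 0.05. Of 50 gene lists, 48 had enough tested genes and were tested with camera at a preset correlation of 0.01. The agreement of the strains' responses was measured by correlations across genes. The groups, comparisons, gene lists, thresholds and other settings were chosen before the data were examined.

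Named genes followed a rule set at the same time. It took protein-coding genes past the threshold with a mean of at least 2 FPKM, ordinary symbols and groups whose libraries did not overlap. From these it named the 8 with the largest change in each direction, or 5 for the strains in hyperoxia. It added up to 4 genes past the threshold from each list, or the 2 most abundant members where none passed, and a set of genes named in every comparison. Not every gene that the rule names is described.

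On simulated data with added changes, the C57 comparison recovered 37.5% of 80 genes changed 1.5-fold, 83.3% of 60 changed 2-fold and 96.7% of 60 changed 4-fold. Of 149 genes called, 7.38% were false, and 0 were called where nothing was changed. The simulation drew each gene independently, with the C57 normoxia means in all groups, and changed only genes above a set number of reads. It held no variation shared between genes, such as that of rod or lens genes, so these rates need not hold for the real libraries.

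There were 14 such settings: other pseudocounts, filters, scalings, model settings and list tests. Each of the 16 libraries was also left out in turn. A further 10 settings were added after seeing the data, among them a sex covariate (log2 of Ddx3y FPKM + 0.1), a covariate of rod gene expression, TPM scaling on the genes of the FPKM filter, limma voom on the recovered reads, protein-coding genes only, libraries of a single sex, and an exact permutation test of list means. Libraries were called male with Xist under 1 FPKM and female with Xist of at least 10 FPKM and Ddx3y under 2 FPKM, limits set after the values were seen. The mean response over both strains was also added after seeing the data. Other splits of the libraries were counted, 35 for each comparison of 8 libraries and 100 drawn for the difference. The software was R 4.3.3, the data.table package (version 1.17.8), Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.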

Results

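RNA sequencing measured gene expression in whole retinas of 12-day-old mice of the C57 and BALBc strains. In the hyperoxia groups, mice breathed 75% oxygen from day 7 to day 12, the vaso-obliteration phase of oxygen-induced retinopathy, in which retinal capillaries regress. The normoxia groups stayed in room air. Each of the 4 groups had 4 libraries. The labels mention a resistant and a susceptible strain without saying which is which, and do not say that the libraries came from separate animals, so p-values measure the spread between these libraries. Values are given as mean ± SD in FPKM (fragment counts scaled for gene length and a library size), n = 4 libraries per group. That size was not the plain number of recovered reads. Recovered reads over it were 0.884 and 0.887 in C57 normoxia replicates 1 and 2, and 1.15 and 1.13 in BALBc hyperoxia replicates 2 and 3. How the size was set, and its effect on the comparisons, was not tested. Whole reads recovered from the FPKM steps came to between 16.7 M and 29.7 M (M, mega) per library, with a median of 20.5 M. In M reads, C57 normoxia replicates 1 to 4 had 20.6, 16.7, 29.7 and 23.3, and the C57 hyperoxia replicates 17.4, 18.2, 19.2 and 20.8. The BALBc normoxia replicates had 20.5, 22.5, 19.1 and 21.6, and the BALBc hyperoxia replicates 19.9, 21.4, 19.6 and 21.9. Of the 54532 genes in the table, 14953 passed the expression filter and were tested.

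Marker genes showed differences between libraries that the groups do not explain. Xist, transcribed from the inactive X chromosome, and the Y-linked gene Ddx3y placed all 4 C57 hyperoxia libraries as female, with Xist between 61.8 and 105 FPKM and Ddx3y listed at 0. C57 normoxia replicates 1 to 3 were male, and replicate 4 held both transcripts, at 60.7 FPKM of Xist and 3.55 FPKM of Ddx3y. BALBc normoxia had male replicates 1 and 2 and female replicates 3 and 4, and BALBc hyperoxia had female replicates 1 to 3 and a male replicate 4, with 1.61 FPKM of Ddx3y beside 45.6 FPKM of Xist in replicate 3, under the limit set for a female library. Rod photoreceptor genes also varied within groups. Gnat1, the rod transducin alpha subunit, was 612, 476, 2924 and 2223 FPKM in the 4 C57 normoxia libraries and between 1051 and 1176 FPKM in C57 hyperoxia. It was between 2275 and 2964 FPKM in BALBc normoxia, and 608, 2575, 2804 and 1095 FPKM in BALBc hyperoxia. The mean log2 value of the lens list ran from -0.49 in C57 hyperoxia replicate 1 to 8.16 in replicate 3 of the same group. Of the list of known strain differences, 3 genes passed the expression filter, and 2 of them, Glo1 and Gabra2, followed the labels. Tyr did not differ in normoxia (limma adjusted p = 0.937), and Nnt and H2-Ea were not among the tested genes. Glo1, carried at higher copy number in some strains, was 184 ± 35.8 FPKM in C57 and 429 ± 16.8 FPKM in BALBc normoxia (log2 difference 1.24, SE 0.14, adjusted p = 2.08e-05). Gabra2, which carries a known regulatory defect in C57 mice, was 2.42 ± 0.518 and 6.12 ± 0.997 FPKM (1.18, SE 0.24, adjusted p = 0.00456).

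**Figure D1:**
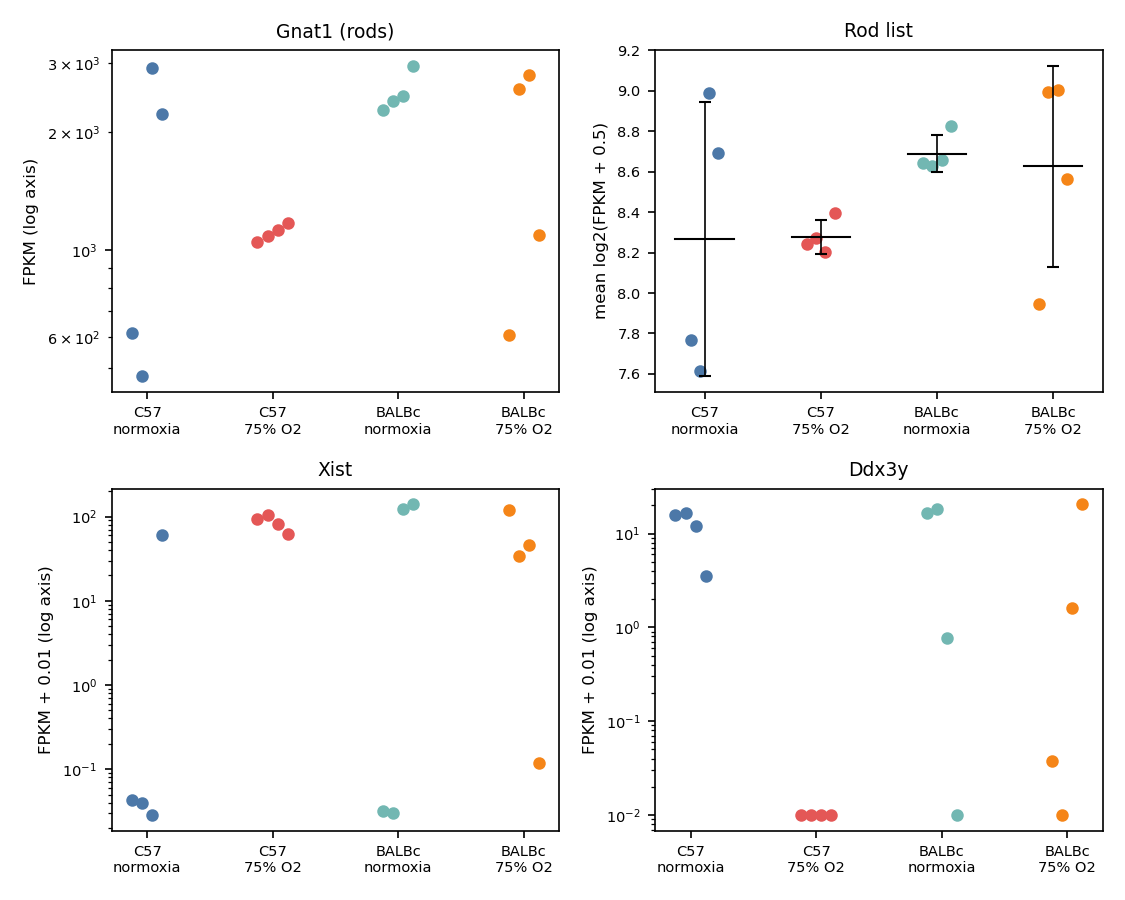
Expression of Gnat1, Xist and Ddx3y (FPKM, log axes; 0.01 added for Xist and Ddx3y) and the rod list mean of log2(FPKM + 0.5), with its group mean and SD as bars, in the 16 libraries (points, replicates 1 to 4 from left to right in each group). All 4 C57 hyperoxia libraries lack Ddx3y, and Gnat1 spans 476 to 2924 FPKM within C57 normoxia.

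The response to hyperoxia in C57 retinas was compared within the strain. limma called 50 genes, 16 higher and 34 lower in hyperoxia, and the 4 libraries of each group did not overlap for any of the 50. Genes past the threshold are selected for such a gap. Over all tested genes the groups did not overlap for 1141 (7.63%, where chance gives 2.86%). Among the higher genes, Ssbp4 (ENSMUSG00000070003, GRCm38 chromosome 8, 70597490 to 70608872), a single-stranded DNA binding protein, went from 18.0 ± 1.85 to 34.5 ± 6.80 FPKM (log2 change 0.90, SE 0.12, adjusted p = 0.0234). Rbm3, a cold-inducible RNA binding protein, rose from 18.9 ± 3.83 to 34.3 ± 7.75 FPKM (adjusted p = 0.0454), and the semaphorin Sema7a from 19.8 ± 2.89 to 33.6 ± 7.62 FPKM (adjusted p = 0.0454). Pnpla2 (ENSMUSG00000025509, chromosome 7, 141455198 to 141460743), the triglyceride lipase ATGL, rose from 3.52 ± 0.178 to 5.70 ± 0.878 FPKM (log2 change 0.61, SE 0.11, adjusted p = 0.0404). Lcn2, a lipocalin of reactive glia, rose by 1.06 on the log2 scale (SE 0.21, adjusted p = 0.0494), and Sesn2, a stress-induced sestrin, by 0.63 (SE 0.12, adjusted p = 0.0454). Plk5 and Lrrc75a rose by 0.90 and 0.71. Hrh3 and Gng13, a histamine receptor and a G protein subunit of ON bipolar cells, rose by 0.76 and 0.74, and Tnnc1 rose by 0.76. Among called protein-coding genes with a mean of at least 2 FPKM, the lower ones named by size were Rgs22 (-1.13), the zinc finger gene Zfp982 (-0.87), the retinal dystrophy gene Cerkl (-0.81), Wdr78 (-0.80), the imprinted gene Mest (-0.70), Fam173b (-0.66), the Golgi complex subunit Cog5 (-0.60) and the zinc transporter Slc39a10 (-0.59). The gene models of Gng13, Tnnc1, Cerkl, Wdr78, Mest, Cog5 and Slc39a10 overlap other genes, and the strand setting of the counting is not given, so their reads cannot be assigned with certainty.

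Vascular genes were lower as a group in C57 hyperoxia. The endothelial list had a median log2 change of -0.46 over 21 tested members, 19 of them below 0 (camera adjusted p = 2.85e-06; adjusted p = 0.308 with an estimated correlation). limma called 0 members over all genes and 5 lower adjusted over the list alone, with 13 lower at an unadjusted p under 0.05. The mural list of pericyte and smooth muscle genes had a median of -0.47 over 9 members (camera adjusted p = 0.00188; adjusted p = 0.308 with an estimated correlation). Its count was 0 over all genes and 4 lower adjusted over the list alone, with 5 lower at an unadjusted p under 0.05. The tight junction gene Cldn5 was 22.7 ± 5.22 FPKM in normoxia and 12.8 ± 1.17 in hyperoxia (-0.78, SE 0.26, adjusted p = 0.193). The pericyte gene Rgs5 was 28.1 ± 2.34 and 13.9 ± 2.97 FPKM (-1.02, SE 0.33, adjusted p = 0.189). Kdr, the main receptor for VEGF, was 20.6 ± 2.89 and 16.7 ± 2.92 FPKM (adjusted p = 0.547). Pecam1 and Cdh5 had log2 changes of -0.46 (adjusted p = 0.36) and -0.75 (adjusted p = 0.208). Vegfa was 32.7 ± 10.9 and 32.5 ± 6.21 FPKM (0.03, SE 0.29, adjusted p = 0.977). Gfap, Rpe65 and Cdkn1a had adjusted p of 0.894, 0.861 and 0.37.

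A further 8 lists passed camera in C57. The circadian clock list had a median log2 change of 0.37 over 14 members (adjusted p = 2.85e-06; adjusted p = 0.308 with an estimated correlation). Its count was 0 over all genes and 7 higher adjusted over the list alone, with 9 higher at an unadjusted p under 0.05, and Tef, a clock output factor, was 27.9 ± 1.64 and 36.4 ± 3.19 FPKM (adjusted p = 0.0636). The clock list mean was 4.05 and 4.06 in C57 hyperoxia replicates 1 and 2, 3.67 and 3.64 in replicates 3 and 4, and between 3.43 and 3.58 in C57 normoxia. The immediate early list had a median of 0.35 (camera adjusted p = 0.00218; adjusted p = 0.308 with an estimated correlation), with 0 members over all genes, 4 higher adjusted over the list alone and 5 higher at an unadjusted p under 0.05. The oxidative phosphorylation list had a median of 0.17 over 69 members (camera adjusted p = 5.15e-06; adjusted p = 0.878 with an estimated correlation), and limma called 0 over all genes and 0 adjusted over the list alone, with 11 higher and 1 lower at an unadjusted p under 0.05. The mitochondrially encoded list had a median of 0.41 (camera adjusted p = 0.0389; adjusted p = 0.878 with an estimated correlation), with 0 calls over all genes, 0 adjusted over the list alone and 1 at an unadjusted p under 0.05. The integrated stress response list and the p53 target list had medians of 0.12 and 0.11 (camera adjusted p = 0.0389 and 0.0259; adjusted p = 0.507 and 0.308 with an estimated correlation). Each had 1 call over all genes, Sesn2, with 1 and 2 higher adjusted over the list alone. Normoxia replicates 1 and 2, low in rod genes, lay below every hyperoxia library in the oxidative phosphorylation (5.63 and 5.43), mitochondrially encoded (7.27 and 7.34) and stress response (3.23 and 3.17) list means. Normoxia replicate 3 (6.11, 8.43 and 3.39) did not, and its oxidative phosphorylation mean was above the 5.80 to 6.06 of hyperoxia. Normoxia replicate 4 was below hyperoxia only in the stress response mean, at 3.34 against 3.38 to 3.45. The sex list had a median of -3.00 over 5 members (camera adjusted p = 0.011; adjusted p = 0.308 with an estimated correlation), with 0 calls over all genes and 1 higher and 4 lower at an unadjusted p under 0.05, the same numbers as adjusted over the list alone. The fatty acid synthesis list is described with the lipid genes. With the sex covariate camera called 11 lists, 5 of them among the 10 called without it, and the mitochondrially encoded, fatty acid synthesis, stress response, immediate early and sex lists were lost. Camera called 10 lists in all, and 9 of the 35 splits of the 8 libraries, the real one included, gave as many.

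The C57 count rested on few libraries: it was 0 without hyperoxia replicate 1 or without normoxia replicate 2, 3 or 4, 2 without normoxia replicate 1, 3 without hyperoxia replicate 2 and 85 without hyperoxia replicate 3. The called genes named for C57 each passed in 7 (Gng13) to 17 (Ssbp4) of 23 or 24 other settings, with highest adjusted p between 0.338 and 0.592. With Ddx3y as a sex covariate, chosen after seeing the data, limma called 0 genes, with 1077 at an unadjusted p under 0.05 against 1987 without it, and scaling to TPM on the same genes, also chosen after seeing the data, gave 7 higher and 47 lower. Where the filter was applied to TPM as well, 20186 genes were tested and the split was 1 higher and 34 lower.

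The same comparison was made in BALBc retinas, where limma called 24 genes, 13 higher and 11 lower in hyperoxia, none with overlapping groups. Over all tested genes the groups did not overlap for 1319 (8.82%, where chance gives 2.86%). The lower genes included endothelial ones. Cldn5 (ENSMUSG00000041378, chromosome 16, 18776847 to 18778262) fell from 12.6 ± 1.70 to 4.86 ± 2.51 FPKM (-1.40, SE 0.26, adjusted p = 0.04). Eng (ENSMUSG00000026814, chromosome 2, 32646595 to 32682669), an endothelial TGF-beta co-receptor whose model overlaps Fpgs, fell from 2.31 ± 0.302 to 0.925 ± 0.381 FPKM (-1.02, SE 0.19, adjusted p = 0.0398). Slc16a3, a lactate exporter, fell from 4.77 ± 0.950 to 2.17 ± 0.502 FPKM (adjusted p = 0.0242), and Ak4, a mitochondrial adenylate kinase induced by hypoxia, from 3.14 ± 0.0889 to 1.62 ± 0.271 FPKM (adjusted p = 0.0374). The matrix gene Efemp1 fell from 5.31 ± 0.519 to 2.66 ± 0.649 FPKM (adjusted p = 0.0257), and the carnitine synthesis gene Tmlhe from 6.42 ± 0.639 to 3.53 ± 0.273 FPKM (adjusted p = 0.00824). Among the higher genes, Snrpg, a spliceosome core protein whose model overlaps Gm44941, rose (log2 change 0.83, SE 0.11, adjusted p = 0.00854), and Atp5mpl, an ATP synthase subunit, from 96.0 ± 11.2 to 178 ± 21.2 FPKM (adjusted p = 0.0398). Sdhd, a succinate dehydrogenase subunit, rose by 0.55 (adjusted p = 0.0305), the ribosomal protein genes Rps27l and Rps15a by 0.74 and 0.56 (both adjusted p = 0.0374), and Sec61g, Cdkn2d and the angiogenesis inhibitor Vash1 by 0.64, 0.60 and 0.59.

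Vascular lists were lower and oxidative phosphorylation genes higher in BALBc hyperoxia. The endothelial list had a median of -0.60 (camera adjusted p = 9.15e-11; adjusted p = 0.332 with an estimated correlation), with 2 lower over all genes and 12 lower adjusted over the list alone. The mural list had a median of -0.47 (camera adjusted p = 0.000155; adjusted p = 0.343 with an estimated correlation), with 0 over all genes, 5 lower adjusted over the list alone and 5 at an unadjusted p under 0.05. Cdh5 was 1.80 ± 0.293 and 0.510 ± 0.399 FPKM (-1.27, SE 0.26, adjusted p = 0.0574), Rgs5 20.1 ± 2.60 and 9.34 ± 5.65 FPKM (adjusted p = 0.109), and Pecam1 1.48 ± 0.143 and 0.817 ± 0.228 FPKM (adjusted p = 0.209). All 69 oxidative phosphorylation genes lay above 0, with a median of 0.50 (camera adjusted p = 2.05e-36; adjusted p = 0.343 with an estimated correlation). limma called 0 of them over all genes and 59 higher adjusted over the list alone, with 62 higher at an unadjusted p under 0.05. Cox8a was 432 ± 33.3 and 699 ± 157 FPKM (adjusted p = 0.166), and Cox6a1 369 ± 35.6 and 558 ± 145 FPKM (adjusted p = 0.209). Shorter genes were higher across the transcriptome: the Spearman correlation across genes of gene length with the log2 change was -0.161, against -0.0376 in C57, where genes are not independent replicates. The TCA cycle list had a median of 0.21 (camera adjusted p = 1.01e-05; adjusted p = 0.343 with an estimated correlation), with 1 higher over all genes, Sdhd, and 7 higher adjusted over the list alone. The mitochondrially encoded and antioxidant lists had medians of 0.43 and 0.22 (camera adjusted p = 0.0178 and 0.0201; adjusted p = 0.635 and 0.582 with an estimated correlation). limma called 0 members of either over all genes, 0 and 1 adjusted over the list alone, and 2 and 5 at an unadjusted p under 0.05. Hyperoxia replicates 2 and 3 carried both, with means of 8.70 and 8.87, and 5.03 and 5.09, against 7.49 and 7.95, and 4.51 and 4.65, in replicates 1 and 4 and 7.48 to 7.94, and 4.52 to 4.75, in normoxia.

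Lists of oxygen-regulated genes, of retinal cells and of other cell types also passed camera in BALBc. The fibroblast and erythroid lists were set beforehand as markers of cells that whole retina should not hold. In no comparison was it tested whether their changes arose in the retina. The hypoxia-inducible factor target list had a median of -0.23 over 22 members (adjusted p = 0.034; adjusted p = 0.343 with an estimated correlation), with 1 lower over all genes, Ak4, and 1 higher and 3 lower adjusted over the list alone. The glycolysis list had a median of -0.22 (adjusted p = 0.000183; adjusted p = 0.395 with an estimated correlation), with 1 lower over all genes, Slc16a3, and 3 adjusted over the list alone. The angiogenic factor list had a median of -0.28 (adjusted p = 0.0135; adjusted p = 0.388 with an estimated correlation), with 0 over all genes, 2 lower adjusted over the list alone and 1 higher and 5 lower at an unadjusted p under 0.05. Its member Vegfa was 26.7 ± 2.33 and 18.7 ± 8.92 FPKM (adjusted p = 0.344). The Müller glia, bipolar, amacrine and fibroblast lists had medians of -0.28, -0.24, -0.25 and -0.51 (camera adjusted p = 0.00107, 9.09e-05, 0.00165 and 0.0342; adjusted p = 0.343, 0.395, 0.395 and 0.395 with an estimated correlation). limma called 0 members of these 4 lists over all genes, 3, 2, 0 and 1 lower adjusted over the list alone, and 6, 3, 3 and 2 lower at an unadjusted p under 0.05. Single libraries stood out: the bipolar list mean was 4.36, 3.31, 3.82 and 4.05 in hyperoxia replicates 1 to 4 against 4.13 to 4.27 in normoxia, and the amacrine mean was 2.43 in hyperoxia replicate 4 against 3.02 to 3.12 in the others. The fibroblast mean was 1.59 and 2.01 in normoxia replicates 2 and 4, while normoxia replicates 1 and 3, at 0.63 and 0.42, overlapped the 0.13 to 0.79 of hyperoxia. Glul, the glutamine synthetase of Müller glia, was 303 ± 11.9 and 180 ± 39.4 FPKM (adjusted p = 0.112). The microglia list had a median of 0.36 (camera adjusted p = 0.000167; adjusted p = 0.343 with an estimated correlation), with 0 over all genes, 5 higher adjusted over the list alone and 6 at an unadjusted p under 0.05. Its mean was 2.46, 2.55, 2.54 and 2.03 in hyperoxia replicates 1 to 4 against 1.88 to 2.13 in normoxia, so replicate 4 was not higher. Hemoglobin and other erythroid genes had a median of -1.76 over 5 members (camera adjusted p = 9.94e-07; adjusted p = 0.332 with an estimated correlation), with 0 over all genes and 5 lower both adjusted over the list alone and at an unadjusted p under 0.05. Hbb-bs was 87.5 FPKM on average in normoxia and 24.9 FPKM in hyperoxia (adjusted p = 0.12), and reads of the globin genes can be shared between near-identical copies. The clock list had a median of -0.09 (camera adjusted p = 0.0427; adjusted p = 0.582 with an estimated correlation), with 0 over all genes, 1 lower adjusted over the list alone and 2 at an unadjusted p under 0.05. Gfap had an adjusted p of 0.725. Camera called 16 lists, and 8 of 35 splits gave as many.

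The BALBc count went to 284 without hyperoxia replicate 1, the library with the lowest Gnat1 of its group, and to 1, 4, 6 and 8 without normoxia replicate 4, hyperoxia replicate 4, normoxia replicate 3 and normoxia replicate 1. It was 108 after scaling to TPM on the same genes, 85 where the filter was applied to TPM as well, 64 after quantile normalization (42 higher and 22 lower), 8 with no filter on low values and 2 among female libraries. The called genes named for BALBc each passed in 12 (Cdkn2d and Vash1) to 23 (Snrpg) of 24 or 25 other settings, with highest adjusted p between 0.0944 and 0.256.

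**Figure D2:**
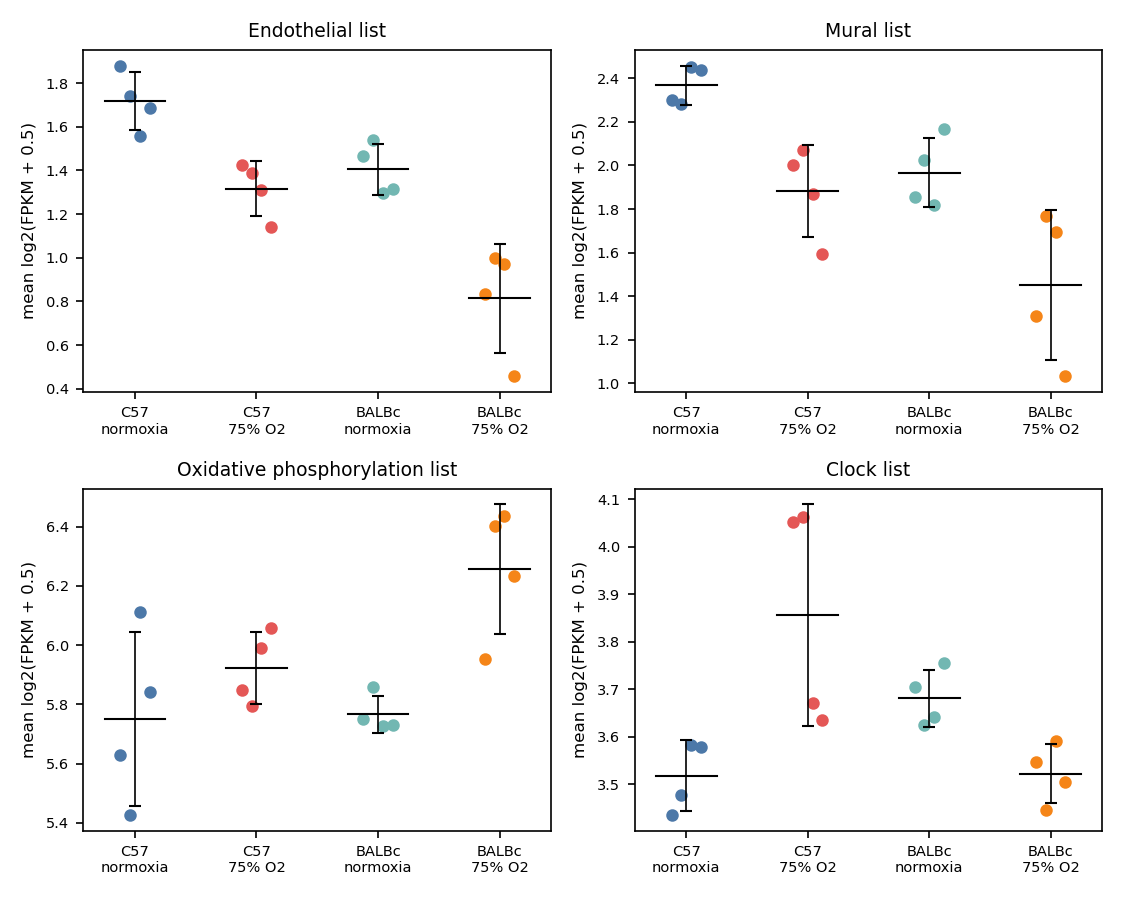
Mean log2(FPKM + 0.5) of the endothelial, mural, oxidative phosphorylation and clock lists in each library (points, replicates 1 to 4 from left to right), with the group mean and SD (bars, n = 4). The median log2 change of the endothelial list was -0.46 in C57 and -0.60 in BALBc, and the clock list stands higher in C57 hyperoxia replicates 1 and 2, at 4.05 and 4.06.

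Whether the strains responded differently was tested with the interaction, the BALBc response minus the C57 response. limma called 0 genes, with 1430 at an unadjusted p under 0.05 and a smallest adjusted p of 0.245. The count was 3473 with library quality weights and 2 with the rod covariate, chosen after seeing the data. The weights ran from 0.33 in BALBc hyperoxia replicate 1 to 3.69 in C57 normoxia replicate 4, the library with both Xist and Ddx3y. Replicates 1 to 3 of C57 normoxia had 0.45, 0.43 and 1.19, so the weighted group rested largely on replicate 4. Cldn5 had a difference of -0.62 (SE 0.36, adjusted p = 0.609), Cdh5 of -0.52 (adjusted p = 0.668), Pecam1 of -0.14 (adjusted p = 0.911), Vegfa of -0.65 (adjusted p = 0.634) and Gfap of -0.46 (adjusted p = 0.795). The endothelial and mural lists did not pass camera (medians -0.14 and 0.05, adjusted p = 0.16 and 0.693). The 0.5 added before the log shrinks changes of genes near it, Cdh5 and Pecam1 in BALBc hyperoxia among them. Differences of such genes between the strains' responses may therefore be held toward 0. The clock list had a median difference of -0.44, all 14 members below 0 (camera adjusted p = 3.35e-08; adjusted p = 0.381 with an estimated correlation), with 0 members over all genes, 5 lower adjusted over the list alone and 7 at an unadjusted p under 0.05. C57 hyperoxia replicates 1 and 2 had clock list means of 4.05 and 4.06, and replicates 3 and 4 of 3.67 and 3.64. The oxidative phosphorylation list had a median difference of 0.31 (camera adjusted p = 2.31e-11; adjusted p = 0.59 with an estimated correlation), with 0 over all genes, 0 adjusted over the list alone and 11 higher at an unadjusted p under 0.05. The TCA cycle and microglia lists had median differences of 0.15 and 0.28 (camera adjusted p = 0.0429 and 0.013; adjusted p = 0.728 and 0.579 with an estimated correlation), with 0 members over all genes and 0 adjusted over the list alone. The hypoxia-inducible factor target and angiogenic lists had -0.24 and -0.17 (camera adjusted p = 0.0116 and 0.00907; adjusted p = 0.381 and 0.509 with an estimated correlation), with 0 members over all genes and 2 and 0 lower adjusted over the list alone. The Müller glia, gliosis, bipolar and amacrine lists had -0.33, -0.38, -0.33 and -0.28 (camera adjusted p = 0.00269, 0.0334, 0.00666 and 0.00666; adjusted p = 0.381, 0.381, 0.59 and 0.579 with an estimated correlation), with 0 over all genes and 3, 0, 2 and 0 lower adjusted over the list alone. The fibroblast and erythroid lists had -0.82 and -1.57 (camera adjusted p = 0.00479 and 0.000326; adjusted p = 0.381 and 0.381 with an estimated correlation), with 0 over all genes and 2 and 1 lower adjusted over the list alone. The fibroblast difference also rested on BALBc normoxia replicates 2 and 4, whose list means were 1.59 and 2.01 against 0.63 and 0.42 in replicates 1 and 3. In C57 that mean was 0.35, 0.98, 0.49 and 1.46 in normoxia replicates 1 to 4 and 1.24 to 1.66 in hyperoxia. Of the TCA cycle, microglia, target, angiogenic, Müller glia, gliosis, bipolar, amacrine, fibroblast and erythroid members, limma gave 6, 1, 3, 3, 4, 1, 3, 2, 2 and 3 an unadjusted p under 0.05. Camera called 12 lists, and 39 of 100 splits gave as many. Leaving out BALBc hyperoxia replicate 3 gave 1 gene, and leaving out any other library gave 0. Across genes, which are not independent replicates, gene length and the log2 difference had Spearman's rho = -0.103. The part of gene length in the list differences was not tested.

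The strains differed in many genes in normoxia. Reads of both strains were aligned to the same reference, GRCm38. Its effect on the strain calls, in normoxia or hyperoxia, was not tested. limma called 1358 genes, 703 higher and 655 lower in BALBc, 467 of them by at least 1 on the log2 scale, and the 4 libraries of each strain did not overlap for 2695 genes (18.0%, where chance gives 2.86%). Rtkn2 (ENSMUSG00000037846, chromosome 10, 67979570 to 68059740) was 0.691 ± 0.0794 FPKM in C57 and 11.8 ± 1.04 in BALBc (3.37, SE 0.13, adjusted p = 6.75e-11). Dnah17, a dynein heavy chain whose model overlaps Pgs1, was 0.279 ± 0.0728 and 6.52 ± 1.30 FPKM (3.16, adjusted p = 9.83e-10), the lysosomal sulfamidase gene Sgsh 2.10 ± 0.420 and 11.6 ± 0.852 FPKM (2.23, adjusted p = 2.6e-08), and Armh4 was higher by 2.44. Guca1a, a guanylate cyclase activator of photoreceptors, was 79.9 ± 43.7 and 382 ± 83.9 FPKM (2.40, SE 0.46, adjusted p = 0.00318). Ppara (ENSMUSG00000022383, chromosome 15, 85734983 to 85802819), the nuclear receptor that drives fatty acid oxidation genes, was 4.54 ± 1.31 FPKM in C57 and 0.0520 ± 0.0240 in BALBc (-3.15, SE 0.21, adjusted p = 4.95e-08). The securin gene Pttg1 was 5.15 ± 1.03 and 0.173 ± 0.163 FPKM (-3.08), the mitochondrial gene mt-Nd3 45.6 ± 6.85 and 4.98 ± 1.19 FPKM (-3.09), and the chemokine gene Ccl27a, which has near-identical copies and overlaps Il11ra1, 10.6 ± 2.41 and 0.228 ± 0.112 FPKM (-3.92). Several named genes have near-identical copies, so their values are uncertain. Rpl29 was 113 ± 24.2 and 0.687 ± 0.484 FPKM (-6.64), and Rpl26, Rps2 and Rps18 were lower in BALBc by log2 differences of -6.32, -5.31 and -3.94. Eno1b was 25.4 ± 4.83 and 277 ± 18.6 FPKM (3.44) while its copy Eno1 was 427 and 270 FPKM, and Eif3j2 and Hmga1b were higher by 2.71 and 2.22.

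By group, endothelial genes were lower in BALBc normoxia, with a median of -0.43 (camera adjusted p = 0.0192; adjusted p = 0.997 with an estimated correlation), 3 lower over all genes and 8 lower adjusted over the list alone. Rasip1, Mfsd2a, the lipid transporter of the blood-retina barrier, and Esam were lower by -0.67, -0.71 and -0.72 (adjusted p = 0.0131, 0.0329 and 0.049), and passed in 23, 15 and 6 of 24 other settings, with adjusted p up to 0.116, 0.111 and 0.411. The rod list had a median of 0.41, all 24 members above 0 (camera adjusted p = 0.0192; adjusted p = 0.997 with an estimated correlation), with 0 over all genes, 0 adjusted over the list alone and 4 higher at an unadjusted p under 0.05. Its mean log2 value was 7.77, 7.62, 8.99 and 8.69 in C57 normoxia replicates 1 to 4 and between 8.63 and 8.83 in BALBc normoxia, so replicates 1 and 2 of C57 carried the difference. The erythroid list had a median of 1.43 (camera adjusted p = 0.0192; adjusted p = 0.997 with an estimated correlation), with 2 higher over all genes, Hbb-bt and Hba-a2, and 5 higher adjusted over the list alone. Hbb-bt passed in 11 of 25 other settings and Hba-a2 in 10 of 24, with adjusted p up to 0.335 and 0.47. The list of known strain differences passed camera (median 1.18, adjusted p = 0.0376; adjusted p = 0.997 with an estimated correlation), with Glo1 and Gabra2, 2 of 3, higher both over all genes and adjusted over the list alone. Among single genes, the cone phosphodiesterase Pde6c was 42.9 ± 13.6 and 9.13 ± 1.54 FPKM (-2.13, adjusted p = 1.84e-05) and the cone opsin Opn1sw, which overlaps Calu, 90.9 ± 16.2 and 163 ± 11.9 FPKM (0.85, adjusted p = 0.00146), while the cone list did not pass (camera adjusted p = 0.912). Pdk1, the pyruvate dehydrogenase kinase induced by hypoxia, was 6.64 ± 0.555 and 2.97 ± 0.121 FPKM (-1.04, adjusted p = 0.000215). Shmt2 and Ndufa4l2, which overlap each other, differed by 1.09 and -1.42. Tyr and Rpe65 had adjusted p of 0.937 and 0.0751. Camera called 4 lists, and 21 of 35 splits gave as many. The gene count was 903 without C57 normoxia replicate 1 and 454 among male libraries only.

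In hyperoxia, limma called 3380 genes between the strains, 1769 higher and 1611 lower in BALBc, 656 of them by at least 1, with 3194 non-overlapping genes (21.4%, where chance gives 2.86%). Endothelial genes were lower, with a median of -0.61 (camera adjusted p = 0.00132; adjusted p = 0.872 with an estimated correlation), 10 lower over all genes, and 1 higher and 11 lower adjusted over the list alone. Cldn5 was 12.8 ± 1.17 FPKM in C57 and 4.86 ± 2.51 in BALBc (-1.43, SE 0.26, adjusted p = 0.00133), Tie1, an endothelial receptor kinase, 1.42 ± 0.542 and 0.400 ± 0.156 FPKM (adjusted p = 0.00934), and Pecam1 and Cdh5 were lower by -0.75 and -0.99 (adjusted p = 0.0199 and 0.0135). The angiogenic list had a median of -0.32 (camera adjusted p = 0.0208; adjusted p = 0.872 with an estimated correlation), with 6 lower over all genes and 6 lower adjusted over the list alone. Vegfa was 32.5 ± 6.21 and 18.7 ± 8.92 FPKM (-0.88, SE 0.29, adjusted p = 0.0369), and passed in 12 of 25 other settings, with adjusted p up to 0.114. Pdgfb and Igfbp3 were lower by -1.19 and -1.64 (adjusted p = 0.000631 and 0.00147). The hypoxia-inducible factor target list had a median of -0.31 (camera adjusted p = 0.0138; adjusted p = 0.672 with an estimated correlation), with 1 higher and 6 lower over all genes and 1 higher and 8 lower adjusted over the list alone. Pdk1 was 4.91 ± 0.560 and 1.81 ± 0.579 FPKM (adjusted p = 2.59e-05), and Ak4 3.63 ± 0.752 and 1.62 ± 0.271 FPKM (adjusted p = 0.000249). The oxidative phosphorylation list had a median of 0.38 (camera adjusted p = 5.15e-06; adjusted p = 0.876 with an estimated correlation), with 24 higher and 1 lower over all genes and 36 higher and 1 lower adjusted over the list alone. Cox6c was 76.3 ± 4.18 and 131 ± 21.5 FPKM (adjusted p = 0.00313), and its model overlaps Vps13b.

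The amacrine and Müller glia lists were lower in BALBc hyperoxia by camera, and the rod list higher. The amacrine list had a median of -0.41, all 17 members below 0 (camera adjusted p = 0.00132; adjusted p = 0.872 with an estimated correlation), with 6 lower over all genes and 8 adjusted over the list alone, among them the transporters Slc17a8 (-1.25, adjusted p = 4.54e-05) and Slc6a9 (-0.48, adjusted p = 0.00241). The Müller glia list had a median of -0.27 (camera adjusted p = 0.0494; adjusted p = 0.876 with an estimated correlation), with 6 lower both over all genes and adjusted over the list alone. Dkk3 was 170 ± 35.5 and 84.2 ± 13.6 FPKM (adjusted p = 0.000365), and Glul 318 ± 105 and 180 ± 39.4 FPKM (adjusted p = 0.0142). The clock list had a median of -0.30 (camera adjusted p = 0.0138; adjusted p = 0.876 with an estimated correlation), with 5 lower over all genes and 6 adjusted over the list alone, Tef, Ciart and Per2 by -0.49, -1.10 and -0.67. C57 hyperoxia replicates 1 and 2, at list means of 4.05 and 4.06, carried most of it. Replicates 3 and 4 were at 3.67 and 3.64, against 3.45 to 3.59 in BALBc hyperoxia. The rod list had a median of 0.42 (camera adjusted p = 0.0489; adjusted p = 0.892 with an estimated correlation), with 3 higher over all genes and 2 adjusted over the list alone. Its mean was 7.95 in BALBc replicate 1, below the 8.20 to 8.40 of C57 hyperoxia, and at least 8.56 in the others. The list of known strain differences had a median of 1.59 (camera adjusted p = 0.0138; adjusted p = 0.672 with an estimated correlation), 2 of 3 higher both over all genes and adjusted over the list alone. Among named protein-coding genes, Eno1b, Rtkn2, Dnah17, Armh4 and Eif3j2 were higher (3.60, 3.57, 2.98, 2.87 and 2.56), and Rpl29, Rpl26, Rps2, Rps18 and Ccl27a lower (-6.97, -5.86, -5.03, -3.86 and -3.77). Camera called 9 lists, and 22 of 35 splits gave as many. After scaling to TPM on the same genes the median of all genes was -0.16 and the split 947 higher and 2079 lower, and with the filter on TPM as well (20186 genes tested) 984 higher and 2180 lower. On the same genes, the median relative to all genes was then -0.80 for the endothelial and 0.37 for the oxidative phosphorylation list. The count was 2102 with the sex covariate and 1784 among female libraries only.

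The oxygen responses of the strains were compared across genes. Across the 14953 genes, which are not independent replicates, the log2 changes had Pearson's r = 0.196 and Spearman's rho = 0.182. Of 100 splits of the libraries, 12 gave an r as high, up to 0.453, so chance was not excluded. r was 0.0849 without C57 normoxia replicate 2, 0.103, 0.110 and 0.131 without C57 hyperoxia replicate 3 or 4 or C57 normoxia replicate 1, 0.283 without C57 hyperoxia replicate 2 or C57 normoxia replicate 3, and 0.309 with the sex covariate. limma called 0 genes in both strains in the same direction, where independent lists would share 0.0139 higher and 0.0250 lower, and the counts at an unadjusted p under 0.05 were 211 higher and 150 lower in both, where independent lists would share 84.5 and 56.6. Of the 50 genes called in C57, 40 had the same sign in BALBc, and of the 24 called in BALBc, 21 had the same sign in C57. Among all tested genes, 56.1% had the same sign in both strains.

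Because the study's title asks about lipid metabolism, 11 lists of lipid genes, 174 tested genes in all, were described together. In C57 hyperoxia, 1 lipid gene was called, Pnpla2, and 27 had an unadjusted p under 0.05. The fatty acid synthesis list passed camera there, with a median of 0.20 over 13 members (adjusted p = 0.0389; adjusted p = 0.878 with an estimated correlation), 0 over all genes, 2 higher adjusted over the list alone and 4 at an unadjusted p under 0.05. Its mean was 3.42, 3.43, 3.68 and 3.75 in normoxia replicates 1 to 4 against 3.70 to 3.80 in hyperoxia, so the difference came mostly from normoxia replicates 1 and 2. In BALBc hyperoxia and in the interaction, limma called 0 lipid genes (14 and 15 at an unadjusted p under 0.05) and no lipid list passed camera, with smallest adjusted p of 0.108 and 0.117. Adjusted over the list alone, the 11 lists held 5 higher in C57, 1 higher in BALBc, and 3 higher and 1 lower in the interaction. These numbers, and those adjusted over the list alone below, are sums over the lists, so a gene in several lists counts in each. Between strains no lipid list passed camera, with smallest adjusted p of 0.161 in normoxia and 0.377 in hyperoxia, while single genes differed in both directions. In normoxia, 5 were higher in BALBc, among them Acacb and Scd1 of the fatty acid synthesis list (adjusted p = 0.000679 and 0.0156) and Mylip, which degrades the LDL receptor (0.84, adjusted p = 0.000351). Acacb lay between 0.326 and 0.460 FPKM in C57 normoxia, below the 0.5 added before the log. The 9 lower ones included the peroxisomal genes Acaa1a, which overlaps Myd88, and Decr2 (-1.13 and -0.90, adjusted p = 0.00167 and 0.00029), the elongase Elovl2 (-0.69, adjusted p = 0.00154), the lipoprotein lipase Lpl (-1.05, adjusted p = 0.000795) and Fabp5 (-1.31, adjusted p = 0.00975). Adjusted over the list alone, the lists held 7 higher and 11 lower. In hyperoxia, 19 were higher and 18 lower in BALBc, and the lists held 19 higher and 17 lower adjusted over the list alone. Over all 14953 tested genes, limma called 1358 between the strains in normoxia and 3380 in hyperoxia. Lipid genes were thus not called more often than tested genes in general. Pnpla2 was 5.70 ± 0.878 FPKM in C57 and 3.12 ± 0.401 in BALBc (-0.77, adjusted p = 0.000139), and Lpl and Dgat2, which makes triglycerides, were lower by -1.12 and -0.94 (adjusted p = 0.000378 and 0.000807). The ketone body genes Acat1 and Oxct1 were higher by 0.64 and 0.71 (adjusted p = 0.0109 and 0.0185), and Oxct1 passed in 17 of 25 other settings, with adjusted p up to 0.0856.

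**Figure D3:**
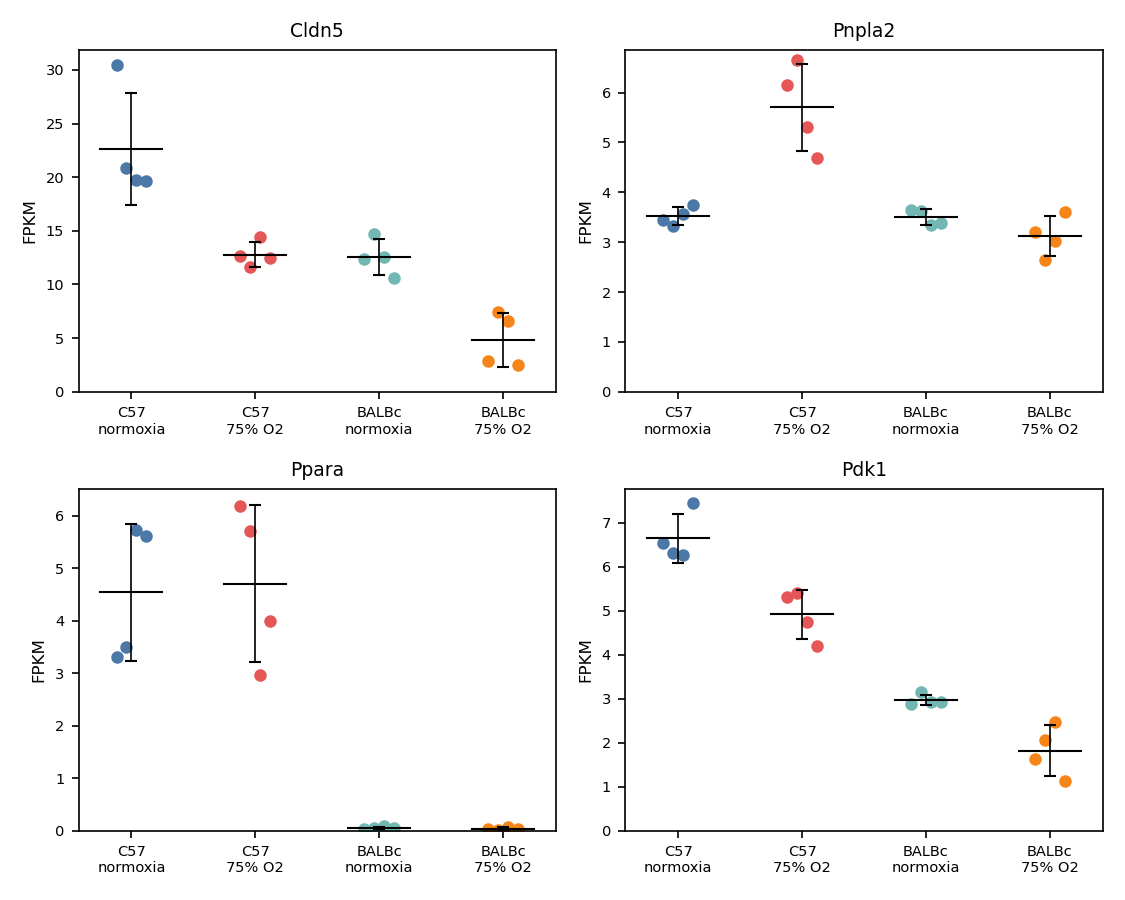
FPKM of Cldn5, Pnpla2, Ppara and Pdk1 in each library (points, replicates 1 to 4 from left to right), with the group mean and SD (bars, n = 4) on axes from 0. Ppara averages 4.54 FPKM in C57 and 0.0520 FPKM in BALBc normoxia, and Cldn5 averages 4.86 FPKM in BALBc hyperoxia.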

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

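The tests of rod share, sequencing depth and pseudogenes, and the counts of other splits, were chosen only after the result was seen, while those of gene length and sex were not.

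Rod genes varied within groups: Gnat1 was 476 and 612 FPKM in C57 normoxia replicates 2 and 1 and 2924 and 2223 FPKM in replicates 3 and 4, and no biological explanation was tested, since the labels give none within a group. Median slopes on the rod list mean within groups were 2.97 for lens, 1.30 for retinal pigment epithelium and 1.25 for pigment genes. They were 1.01 for mitochondrially encoded genes and -0.50 for bipolar genes. A slope grows with the spread of a list, and no SE or correlation was taken for these lists. In C57 hyperoxia the lens list mean ran from -0.49 to 8.16 while the rod list mean stayed between 8.20 and 8.40. A different share of rod cells alone would scale all rod genes alike, but 15 of 24 rod genes had slopes on the rod list mean more than 2 SE from 1. Each gene is part of that mean, so the slopes average 1 by construction and members under 1 push others over 1. The count therefore cannot exclude a different share of rod cells as part of the cause. Gene length bias was argued against by a median slope of 0.0385 in genes matched in length to the rod genes. Sequencing depth stays open: within groups the rod list mean and log2 recovered reads had Pearson's r = 0.714 (permutation p = 0.0321, 16 libraries) and Spearman's rho = 0.444 (permutation p = 0.178), and r was 0.373 without the 2 libraries farthest in depth.

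The C57 groups differed in sex by expression, with all 4 hyperoxia libraries female and normoxia replicates 1 to 3 male. If sex were the whole cause of the 50 calls, the called genes should differ between female and male BALBc libraries in the same way. Their median difference there, in the direction of the C57 change, was 0.0151 (SD 0.164 over genes) against a median C57 change of 0.738, and 28 of 50 had that direction. With the sex covariate the median size of the 50 changes went from 0.738 to 0.698 and the median SE from 0.138 to 0.198, and all 50 had the same sign. The calls ended because the SE grew. Ddx3y was 0 FPKM in all 4 C57 hyperoxia libraries and varied less within C57 normoxia than within the BALBc groups. The effect of the covariate was therefore estimated mostly from BALBc libraries. The kept sizes and signs thus repeat the BALBc result and cannot separate sex from oxygen in C57. A sex effect specific to C57 stays open.

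Pseudogenes were called between the strains in normoxia more often than other genes, 17.2% of 893 against 8.56% (odds ratio 2.23, Fisher's exact p = 2.12e-15), and 74.7% of these calls were higher in BALBc. In hyperoxia 223 of 893 pseudogenes were called, and 22.5% of other genes (odds ratio 1.15, Fisher's exact p = 0.0832). Of 20 called pseudogenes named after a tested parent gene, 15 had a parent with a difference of the opposite sign (exact binomial p = 0.0414), and counting each parent once it was 13 of 15 (exact binomial p = 0.00739). Among the 13 pairs whose parent was called, 8 were opposite and 5 the same (exact binomial p = 0.581), or 7 of 9 parents (exact binomial p = 0.18), so whether reads were shared between genes and their copies stays open. A true difference between strains, which the design names, stays open as untested.

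Single libraries stood apart from the others of their group in 20 of 428 groups tested (4.67%), where chance flags about 1 in 20 (5%). The value is the gap to the nearest library over the group's range. In C57 normoxia these were Acacb (0.936) and Cldn5 (0.892) in replicate 1, Hba-a2 (0.964) in replicate 3, and Dkk3 (0.956) and Xist (0.9998) in replicate 4, all highest. In C57 hyperoxia they were Eif3j2 in replicate 2 (0.916) and Fabp5 in replicate 3 (0.893), both highest. BALBc normoxia replicate 4 was lowest for Ccl27a (0.909) and Cog5 (0.881) and highest for Glul (0.878), Vtn (0.887) and the rod list mean (0.845). Replicate 2 of that group was highest for Cdkn1a (0.853) and Pdk1 (0.855), and replicate 1 lowest for Rasip1 (0.873). In BALBc hyperoxia, replicate 1 was lowest for Acat1 (0.846) and Armh4 (0.901), replicate 3 highest for Hba-a2 (0.906) and Rpl26 (0.910), and replicate 4 highest for Ddx3y (0.922).

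Camera with the preset correlation called 12 lists on the interaction of strain and oxygen, while 0 lists were called with an estimated correlation (smallest adjusted p = 0.381) or with fry (smallest adjusted p = 0.152). The median differences, BALBc minus C57, were -0.82 for fibroblast, -0.33 for Müller glia, -0.38 for gliosis, 0.28 for microglia, -0.33 for bipolar, -0.28 for amacrine, -1.57 for erythroid, -0.24 for hypoxia-inducible factor target, -0.17 for angiogenic, 0.15 for TCA cycle, 0.31 for oxidative phosphorylation and -0.44 for clock genes. Of 100 splits, 39 gave at least 12 lists, and the highest other gave 22, so chance was not excluded.

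Other splits of the libraries, the real one included, tested the remaining counts. For the 50 genes of C57 hyperoxia, 2 of 35 splits gave as many, so chance was not excluded. The other one gave 493 genes, several times the real count, with hyperoxia replicates 1 and 2 and normoxia replicates 1 and 2 on one side, which points to a structure of the samples other than oxygen. The lens list mean was -0.49, -0.02, 3.08 and 1.98 in those libraries. It was 8.16 and 4.69 in hyperoxia replicates 3 and 4, and 4.39 and 5.62 in normoxia replicates 3 and 4. Only the real split gave as many for the BALBc count of 24 (1 of 35, highest other 6). The same held for the strain counts of 1358 in normoxia (1 of 35, highest other 2) and 3380 in hyperoxia (1 of 35, highest other 134). With 35 splits the share cannot fall below 1 of 35, and it was not adjusted for the number of counts tested. For the 0 genes of the interaction the count of splits (100 of 100, highest other 361) was fixed by the 0 and says nothing about chance. Chance was not excluded for the agreement of r = 0.196 (12 of 100, highest other 0.453). Nor was it for the list counts of 10 in C57 (9 of 35, highest other 13), 16 in BALBc (8 of 35, highest other 24), 4 between strains in normoxia (21 of 35, highest other 15) and 9 in hyperoxia (22 of 35, highest other 22).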

How the results depend on the processing

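The settings with the sex or rod covariate, TPM scaling on the same genes, voom, protein-coding genes, libraries of a single sex, fry with a covariate, and exact permutation were chosen only after the result was seen. Where no cause is given, the cause was not tested.

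For C57 hyperoxia against normoxia, the 50 calls became 32 with a pseudocount of 0.1, 9 with no filter on low values, 29 with a filter of 5 FPKM, 99 with quantile normalization, 16 without the mean-variance trend, 1 with the replicate block, 0 with the sex covariate, 430 with the rod covariate, 14 with voom and 1 with only the 8 libraries compared. For BALBc hyperoxia against normoxia, the 24 calls became 8 with no filter, 108 with TPM scaling on the same genes, 85 with the filter on TPM too, 64 with quantile normalization, 39 with the sex covariate, 802 with the rod covariate, 138 with voom, 47 with protein-coding genes only, 3 with only the 8 libraries compared and 2 with female libraries only (fewer samples). Between strains in normoxia, 1358 calls became 454 with male libraries only, and in hyperoxia 3380 became 2102 with the sex covariate, 2003 with only the 8 libraries compared and 1784 with female libraries only. The interaction had 2 calls with the rod covariate. Library quality weights gave 2798, 2457, 3473, 3110 and 6800 calls in C57, BALBc, the interaction, normoxia and hyperoxia. These weights were uneven, from 0.33 in BALBc hyperoxia replicate 1 to 3.69 in C57 normoxia replicate 4. Requiring a log2 change of 1 left 12, 7, 467 and 656 calls in the comparisons other than the interaction.

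With an estimated correlation camera called 0 lists in each of the 5 comparisons. fry called 1 list in C57, 5 in BALBc, 0 in the interaction and 2 between strains in normoxia and 9 in hyperoxia, and with the sex covariate 0, 4, 0 and 1, and 3 in hyperoxia. fry with the rod covariate called 8 lists in C57, 16 in BALBc, 3 in the interaction, and 6 in normoxia and 17 in hyperoxia between strains. Camera called 14 lists between strains in hyperoxia with the replicate block and 7 in normoxia with the sex covariate. Exact permutation of list means gave 0 lists in C57, BALBc, and both strain comparisons, but with 4 against 4 libraries its smallest p is 0.0286, so the adjustment over 48 lists left little room for a call. The agreement r was 0.309 with the sex covariate. The mean response had 15 calls with the sex covariate and 1287 with the rod covariate.

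Leaving out each library in turn gave between 0 and 85 calls in C57, 1 and 284 in BALBc, 0 and 1 in the interaction, 903 and 1398 between strains in normoxia, 2326 and 4244 in hyperoxia, 89 and 484 for the mean response, and an agreement r between 0.0849 and 0.283. For the named genes, 2819 values stayed on their side of the threshold, 479 lost the threshold, 36 gained it and 0 reversed. A change of sign counted as reversed only where the main or the other setting passed the threshold. The 2819 can therefore hold changes of sign where neither passed. The planned negative binomial model was meant for deposited raw counts and was not run, because the table holds FPKM. On the recovered reads only limma voom was run. Single-sex libraries gave no value for C57, whose groups share no sex. Depth of 16.7 M to 29.7 M (mega) reads limits genes near 1 FPKM.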

Other observations

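The mean response and the test of PPAR target genes were chosen only after the result was seen, and the genes named here were chosen after their values were seen.

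The response to hyperoxia averaged over both strains was not tested by list. limma called 268 genes for the mean response, 156 higher and 112 lower, with 2594 at an unadjusted p under 0.05. The lower ones included 6 of 21 endothelial and 3 of 9 mural genes, and the higher ones 23 of 80 ribosomal protein genes and 10 of 69 oxidative phosphorylation genes. Shorter genes were higher in the BALBc response (Spearman's rho = -0.161 across genes), and the part of gene length in these counts was not tested. Cldn5 had a mean log2 change of -1.09 (SE 0.18, adjusted p = 0.0132), Rgs5 of -1.15 (SE 0.23, adjusted p = 0.0271), the apelin receptor gene Aplnr of -0.93 (SE 0.14, adjusted p = 0.0121) and Kcnj8, a pericyte potassium channel, of -0.81 (SE 0.15, adjusted p = 0.0186). Among higher genes, Egr1 had 0.90 (SE 0.18, adjusted p = 0.023), and the cholesterol exporter Abca1 0.59 (SE 0.12, adjusted p = 0.0292). Of 100 splits, 1 gave as many genes, the real one, and the highest other gave 221. With 100 splits the share cannot fall below 1 of 100. With the sex covariate 15 genes were called, 6 higher and 9 lower, 14 of them shared, among them Aplnr (adjusted p = 0.021) and Kcnj8 (adjusted p = 0.0453). The count was 475, 117, 112 and 143 without BALBc hyperoxia replicates 1 to 4, and 110, 107 and 99 without BALBc normoxia replicates 1, 3 and 4. It was 118 and 134 without C57 hyperoxia replicates 1 and 4, and 123, 89, 484 and 134 without C57 normoxia replicates 1 to 4.

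Ppara was near 0 in every BALBc library group, at 0.0520 FPKM in normoxia and 0.0379 FPKM in hyperoxia, against 4.54 and 4.71 FPKM in C57. A candidate explanation for strain differences in lipid genes is a lower output of PPAR alpha target genes. The target list had a median difference of 0.0294 in normoxia (camera adjusted p = 0.912), and members went both ways, so this could not be told from the test. The neighbouring genes Atxn10, Cdpf1, Ttc38, Trmu and Gramd4 were not called (adjusted p = 0.163, 0.934, 0.903, 0.63 and 0.547).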
